A study of Boehmeria nivea with 10 samples.

How the data were processed

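The series held 10 samples of ramie (Boehmeria nivea) root RNA. Per the labels, 3 were roots formed in water on 5-day-old seedlings (early hydroponic), 3 were roots formed in water on 30-day-old seedlings (late hydroponic) and 3 were roots of 30-day-old seedlings grown in soil (terrestrial). The remaining sample was 1 pool of aquatic and terrestrial stages. Per the series' design text, the pool was sequenced on an Illumina HiSeq instrument and assembled de novo into the contigs that served as the reference, while the 9 separate samples were quantified on a BGISEQ instrument. The pool entered no comparison, and its expression values were not used here. Per the labels' protocols, the roots were flash frozen and their RNA was isolated with Trizol. The assembler, aligner and counting program and their versions were not given in the sources used here, and neither was the strandedness of the libraries.

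Per the file headers, the authors' deposited table of each of the 9 samples gave a contig identifier, a contig length, an expected count and an FPKM value. The deposited expected counts are estimates that need not be whole where reads match several contigs, and between 74.7 and 75.4% of the listed values were whole in each library. The deposited FPKM values are expected counts per kilobase of contig, scaled to the library's reads. The listed counts summed to 97.2 to 97.4% of the library size that the FPKM values imply. Each table listed only part of the contigs, and a contig listed in another library was entered as 0. That an unlisted contig had no reads is an inference, which the tables do not state, and the contigs found in 1 group alone rest on it. The 9 tables named 40300 contigs with a median length of 629 bases (range 200 to 15684), of which 9202 carried 1 of 4027 cluster numbers and 31098 carried none. Contigs of 1 cluster can be alleles, splice forms or close paralogues, and a contig can be a fragment, so contig counts are not gene counts. The tables pair no identifier with a gene name or description, and no reference of the species was used here. The gene lists drawn up before the data were examined could therefore not be tested, and no function is given for any contig.

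Groups were taken from the labels. The total of listed expected counts ran from 9499903 to 11522430 per library. The labels do not say whether the 3 libraries of a group came from separate plants. The p-values weigh differences between groups against the spread between these samples, which may be partly technical. If it is, they are too small for statements about plants in general. No library was a copy of another, since replicate pairs differed by a chi-square of 8.8 to 41.7 per degree of freedom. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling. The filter was filterByExpr on the groups, with its minimum count of 10, and it kept 26747 contigs. The 3 groups were fitted together with robust quasi-likelihood dispersions and 6 residual degrees of freedom, with no block and no covariate. A contig was called changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all contigs tested, separately in each comparison. Fold changes are on the log2 scale. Their standard errors (SE) were derived as the absolute change divided by the square root of the quasi-likelihood F statistic. They therefore restate the test and are no separate estimate of precision. FPKM levels are means with standard deviations (SD) over 3 libraries.

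The rule for named contigs was fixed before the data were examined. A named contig passed the threshold, had a mean of at least 10 FPKM over the 9 libraries and a value above 0 in every library of both groups, and had every library of 1 group above every library of the other. The first 2 higher and the first 2 lower by size of the fitted change were named in each comparison. Ratios of summed counts with 95% exact binomial intervals were added where a group held few counts, and these intervals cover counting error only. Principal components and correlations between libraries were computed on log2 CPM with a prior count of 2. Correlations between libraries run across contigs, which are not independent replicates. Values per library were compared with exact two-sided permutation tests in SciPy 1.17.1, whose smallest p with 3 against 3 libraries is 0.1. Cluster numbers were shuffled over the tested contigs 1000 times, and the share among clusters with at least 2 called contigs was added after the data were seen. Unchanged groups that share the terrestrial libraries were simulated 10 times to give the overlap of calls with no effect present. Contigs that set 1 group apart from both others were those called in the same direction against each of them, and the early and late hydroponic sets were not among the results planned.

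EdgeR's test, DESeq2, limma on log2(FPKM + 1) and limma voom were tried on simulated data with 200 contigs changed. The count of clusters with members called in opposite directions was tried on 30 planted clusters and found 30. The remaining tests were not tried in this way. The median ratio of edgeR's estimated to true log2 change was 0.981 for late hydroponic against terrestrial, 0.997 for late against early hydroponic and 1.014 for early hydroponic against terrestrial. Of the contigs changed 4-fold, edgeR recovered 72.7% in the first, 42.4% in the second and 62.1% in the last of these, and of those changed 2-fold it recovered 7.5%, 7.5% and 9%. Far more contigs were called in the data, where the Benjamini-Hochberg cut-off was therefore less strict, so these shares do not give the recovery of the reported fits. A first criterion for the share recovered at 4-fold was not met and was replaced by bounds on the slope and on false calls. There were 1, 2 and 2 false edgeR calls among 57, 35 and 49. DESeq2, one of the alternatives, made 63, 55 and 67 false calls among 158, 137 and 163 in the same simulations.

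The alternatives were other scalings (DESeq2's size factors, library totals, upper quartile), DESeq2 1.42.0, and limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) and with voom. Others were no count filter, a minimum of 50 counts in 3 libraries, contigs under 500 bases left out, a fold threshold, only the 2 groups compared, the replicate number as a block and each library left out in turn. These were fixed before the data were examined. A further 3 alternatives were added after the data were seen: late hydroponic replicate 3 and terrestrial replicate 2 left out together, contigs with under 3 counts throughout a group left out, and DESeq2 restricted to the 26747 contigs. The other calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.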

Results

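Ramie is a perennial bast-fibre crop of the nettle family. RNA of its roots was sequenced to follow how expression changes as roots form in water and adjust to it. There were 3 libraries of early hydroponic roots (5-day-old seedlings), 3 of late hydroponic roots (30-day-old seedlings) and 3 of terrestrial roots (30-day-old seedlings in soil). The listed expected counts summed to 11522430, 11424582 and 11466215 in early hydroponic replicates 1, 2 and 3, to 9878863, 9499903 and 10328909 in the late hydroponic ones and to 10702907, 10606839 and 10473340 in the terrestrial ones. Between 33480 and 35313 contigs were listed per library, and 26983 were listed in all 9. Contigs are named by the assembly's identifiers, which the tables pair with no gene name.

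Terrestrial roots stood apart from both kinds of hydroponic root along the first principal component, which held 61.6% of the variance. Early and late hydroponic roots separated along the second, which held 17%. Correlation across contigs averaged 0.962 between early libraries, 0.933 between late libraries and 0.949 between terrestrial libraries. It averaged 0.888 between early and late hydroponic libraries, 0.76 between late hydroponic and terrestrial libraries and 0.721 between early hydroponic and terrestrial libraries. The mean correlation of a library with the terrestrial ones was 0.761 ± 0.004 (SD, n = 3) for late and 0.721 ± 0.005 (SD, n = 3) for early hydroponic roots, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give. Late hydroponic replicate 3 lay at -52.62 on the second component, against -113.92 and -95.99 for late replicates 1 and 2 and 60.62 to 75.76 for the early libraries.

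**Figure D1:**
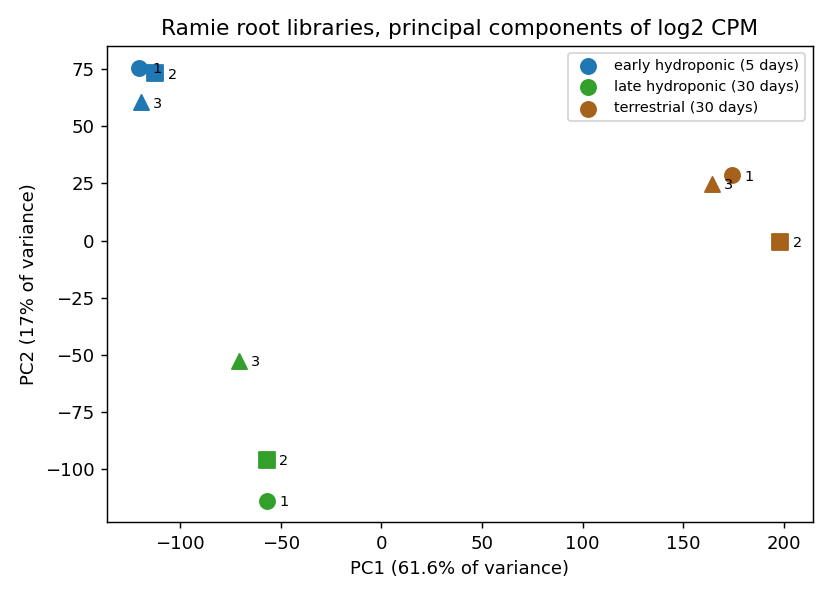
Principal components 1 (x axis, 61.6% of variance) and 2 (y axis, 17%) of log2 CPM over the tested contigs, in component units, with 1 point per library, colour for the group and shape and number for the replicate. The 3 terrestrial libraries lie at 164.02 to 198.22 on component 1, and late hydroponic replicate 3 lies nearer to the early libraries on component 2 than late replicates 1 and 2 do.

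Late hydroponic against terrestrial roots compared growth in water with growth in soil at 1 stated seedling age. Of 26747 contigs tested, 7685 were higher and 6475 lower in late hydroponic roots, 52.9% in all, and the change was 2-fold or more in 5506 of the higher and 4071 of the lower ones. The largest rises by the naming rule were in Unigene20764_mixA, a contig of 10048 bases at 283 ± 407 FPKM in late hydroponic and 0.14 ± 0.01 FPKM in terrestrial roots (SD, n = 3), and in Unigene10184_mixA, of 648 bases, at 735 ± 485 FPKM against 0.65 ± 0.38. The largest falls were in Unigene31091_mixA, of 1757 bases, at 0.06 ± 0.01 FPKM in late hydroponic and 128 ± 94.0 FPKM in terrestrial roots, and in Unigene21847_mixA, of 1945 bases, at 0.27 ± 0.02 against 121.5 ± 64.2 FPKM. In each of these contigs all 3 libraries of the higher group lay above all 3 of the lower, as the naming rule requires.

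Unigene20764_mixA rose by 11.10 ± 2.06 (SE) and Unigene10184_mixA by 10.16 ± 0.83 on the log2 scale, with adjusted p = 0.00237 and 5.69e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Unigene31091_mixA changed by -10.86 ± 1.29 and Unigene21847_mixA by -8.65 ± 0.68, with adjusted p = 0.000729 and 4.98e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Unigene20764_mixA was uneven among late libraries, at 752.83, 65.75 and 30.87 FPKM in replicates 1, 2 and 3, and its log2 change without late replicate 1 was 8.53. Unigene31091_mixA had 1 count in each late library and was not listed in the early ones. Its ratio of summed counts, terrestrial to late, was 2100, with a 95% counting interval of 720 to 10200. Its terrestrial level was 168.61, 20.81 and 195.43 FPKM in replicates 1, 2 and 3. Unigene10184_mixA had 2 to 7 counts per terrestrial library, and its ratio, late to terrestrial, was 1180 (95% counting interval 691 to 2220). Unigene21847_mixA had 5 to 6 counts per late library, and its ratio, terrestrial to late, was 415 (256 to 727). The expected counts of Unigene21847_mixA were whole in 5 of 9 libraries, so part of its reads was shared with other contigs. Over the called contigs the median log2 change was 1.58 for the higher and -1.23 for the lower ones, and 933 higher and 390 lower contigs changed 16-fold or more. Of the changed contigs 54.3% were higher with TMM scaling, and the majority turned with library totals alone (49.6%, 7051 higher and 7159 lower), with upper quartile scaling (49%) and with limma on log2(FPKM + 1) (47.7%). A test against a change of 1.5-fold (glmTreat) called 8892 contigs.

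**Figure D2:**
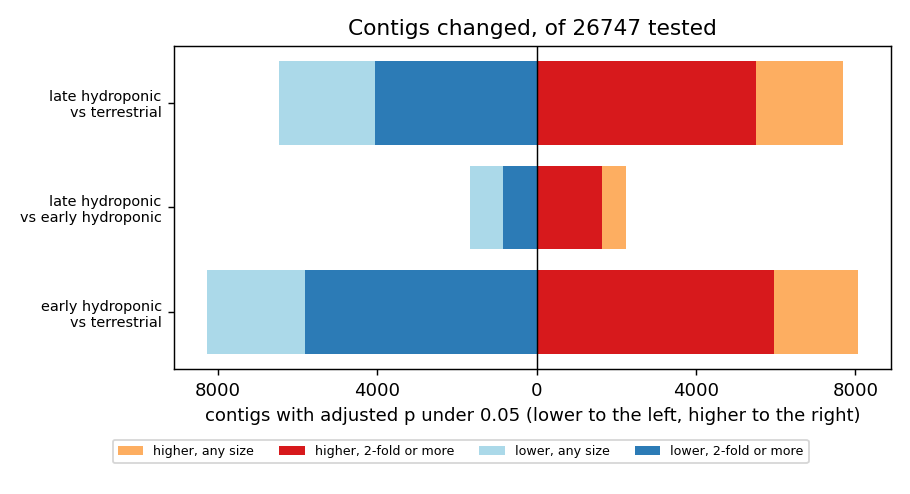
Number of contigs with adjusted p under 0.05 in each comparison (x axis, of 26747 tested), lower to the left and higher to the right of 0, with the darker part of each bar for changes of 2-fold or more. The bars for late hydroponic against terrestrial roots reach 6475 lower and 7685 higher contigs, and those for late against early hydroponic roots reach 1684 and 2238.

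Late against early hydroponic roots compared a later with an earlier stage of roots in water, which differ in seedling age as well. Fewer contigs were called here than in either comparison with soil: 2238 were higher and 1684 lower at the late stage, 14.7% of those tested. The largest rises by the naming rule were in CL1031.Contig2_mixA, of 3755 bases, at 632 ± 312 FPKM late and 0.57 ± 0.87 FPKM early (SD, n = 3), and again in Unigene10184_mixA, at 735 ± 485 against 0.79 ± 0.89 FPKM. Both were low in terrestrial roots too, at 1.71 ± 1.29 and 0.65 ± 0.38 FPKM. The largest falls were in Unigene25911_mixA, of 960 bases, from 200.2 ± 149 FPKM early to 3.55 ± 3.4 late, and in Unigene32302_mixA, of 1554 bases, from 115 ± 24.4 to 3.3 ± 1.55 FPKM, with 36.6 ± 10.3 FPKM in terrestrial roots.

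CL1031.Contig2_mixA rose by 9.99 ± 1.32 (SE) and Unigene10184_mixA by 9.68 ± 0.81 on the log2 scale, with adjusted p = 0.00405 and 0.00145 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Unigene25911_mixA changed by -5.94 ± 0.85 and Unigene32302_mixA by -5.25 ± 0.4, with adjusted p = 0.00524 and 0.00113 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all of these contigs the 3 late libraries lay on 1 side of the 3 early ones, as the naming rule requires. CL1031.Contig2_mixA had 1 to 69 counts per early library, and its ratio of summed counts, late to early, was 1010 (95% counting interval 810 to 1290). Unigene10184_mixA had 1 to 13 counts per early library, and its ratio was 833 (520 to 1430). The log2 change of CL1031.Contig2_mixA was 12.96 without early replicate 3 and 9.40 without late replicate 3, and that of Unigene10184_mixA was 11.10 without early replicate 3 and 9.03 without late replicate 2. Unigene25911_mixA changed by -5.13 without early replicate 2 and by -6.98 without late replicate 1. CL1031.Contig2_mixA belongs to a cluster whose contigs can share reads, and its expected counts were whole in 7 of 9 libraries.

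Among the contigs changed between the hydroponic stages, the median log2 change was 1.69 for the higher and -1.02 for the lower ones, and 387 higher and 89 lower contigs changed 16-fold or more. The share of changed contigs that were higher late was 57.1% with TMM scaling, 75.5% with library totals alone (3249 higher, 1052 lower) and 71.5% with limma on log2(FPKM + 1), and without late replicate 3 it was 46.7% (2656 higher, 3031 lower). It was 50.1% with DESeq2's size factors in edgeR, 49.6% with DESeq2, 48% with limma voom and 47.7% with contigs under 500 bases left out, so which direction held the majority depended on the setting. Library totals moved the median log2 change of all tested contigs from 0.04 to 0.18 here, from -0.09 to -0.32 for early hydroponic against terrestrial roots and from 0.02 to -0.07 for late hydroponic against terrestrial roots, and changes are given relative to the TMM scale. The number of calls moved from 3922 to 1598, 1847 and 1728 without early replicate 1, 2 and 3, to 1967 and 2038 without late replicate 1 and 2, and to 5687 without late replicate 3. It was 2495 with a change of at least 1 on the log2 scale, 1269 by glmTreat against 1.5-fold, and 7145 without late hydroponic replicate 3 and terrestrial replicate 2, an alternative added after the data were seen.

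Early hydroponic against terrestrial roots differed in growth medium and in seedling age together. Of the tested contigs 8064 were higher and 8283 lower in early hydroponic roots, 61.1% in all, with 2-fold changes or more in 5964 and 5820. The largest rises by the naming rule were in Unigene17302_mixA, of 975 bases, at 2431 ± 297 FPKM in early hydroponic and 3.72 ± 4.04 FPKM in terrestrial roots (SD, n = 3), and in CL1499.Contig1_mixA, of 1329 bases, at 104 ± 16.7 against 0.44 ± 0.16 FPKM. The largest falls were in Unigene6328_mixA, of 586 bases, at 0.31 FPKM in each early and 2517 ± 974 FPKM in terrestrial libraries, and in Unigene25518_mixA, of 507 bases, at 0.6 ± 0.27 against 1573 ± 409 FPKM. Late hydroponic roots lay between the other groups in Unigene17302_mixA (674 ± 349 FPKM), CL1499.Contig1_mixA (53.3 ± 1.19 FPKM) and Unigene25518_mixA (8.72 ± 5.8 FPKM).

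Unigene17302_mixA rose by 9.60 ± 0.93 (SE) and CL1499.Contig1_mixA by 8.06 ± 0.24 on the log2 scale, with adjusted p = 6.38e-05 and 1.26e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Unigene6328_mixA changed by -12.67 ± 2.72 and Unigene25518_mixA by -11.08 ± 0.69, with adjusted p = 0.00385 and 1.15e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In each contig the 3 early libraries lay on 1 side of the 3 terrestrial ones, as the naming rule requires. Unigene6328_mixA had 2 counts in each early library, and its ratio of summed counts, terrestrial to early, was 6910 with a 95% counting interval of 3180 to 18800. In late hydroponic replicates 1, 2 and 3 it stood at 0.18, 0.19 and 212.63 FPKM. Unigene25518_mixA had 2 to 5 counts per early library, and its ratio, terrestrial to early, was 2230 (95% counting interval 1210 to 4640). CL1499.Contig1_mixA had 5 to 8.7 counts per terrestrial library, and its ratio, early to terrestrial, was 272 (174 to 452). The log2 change of Unigene17302_mixA without terrestrial replicate 3 was 10.98. The expected counts of CL1499.Contig1_mixA were whole in 0 of 9 libraries, so its level depends on how shared reads were divided among contigs. Over the called contigs the median log2 change was 1.64 for the higher and -1.44 for the lower ones. The share of changed contigs that were higher was 49.3% with TMM scaling, 40.1% with library totals alone (6780 higher, 10132 lower) and 39.0% with limma on log2(FPKM + 1), and it was 50.8% with DESeq2's size factors in edgeR, 53% with DESeq2 and 53.8% with no count filter.

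**Figure D3:**
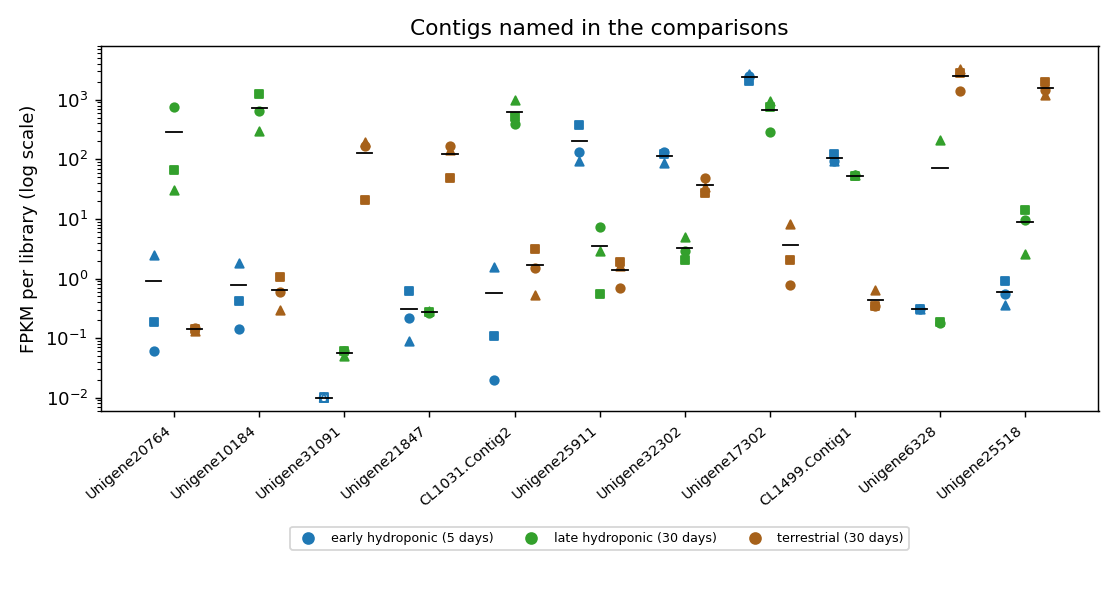
FPKM (y axis, log scale) of the named contigs in each of the 9 libraries, with colour for the group, circles, squares and triangles for replicates 1, 2 and 3 a line at each group's mean and open symbols at the foot of the axis for libraries that do not list the contig. Late hydroponic replicate 3 stands at 212.63 FPKM in Unigene6328_mixA, against 0.18 and 0.19 FPKM in late replicates 1 and 2.

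A set of 11890 contigs differed from terrestrial roots in the same direction at both hydroponic stages. Of these, 6344 were higher in water at both stages, with a median log2 change of 1.82 early and 1.58 late, and 5546 were lower, with medians of -1.52 and -1.28. Median FPKM in the higher set was 18.17 early, 16.89 late and 5.48 in terrestrial roots, and in the lower set 5.3, 7.09 and 20.12. Most of these contigs, 10278, were not called between the hydroponic stages. Where they were, 1369 lay closer to the terrestrial level at the late stage and 243 lay further from it. The contigs were chosen for called changes against terrestrial roots at both stages, and the late against early comparison uses the same hydroponic libraries. Noise in the early libraries favours the closer count, and noise in the late libraries favours the further count. How many would lie closer with no change between the stages was not tested.

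Both comparisons used the same 3 terrestrial libraries. In 10 simulations of unchanged groups that share them, the highest overlap was 0 contigs and the highest number of calls in a comparison was 1. With so few calls the overlap had almost no room to rise above 0, so the simulations do not give the overlap that shared controls add where real changes are present. Independent lists of the observed lengths would share 2317 higher and 2005 lower contigs. With 3 terrestrial libraries the controls could not be split, so part of the excess may come from sharing them. The higher set outnumbered the lower one with TMM scaling, while library totals alone gave 5503 higher and 6515 lower contigs. The overlap was 7831 contigs with a change of at least 1 on the log2 scale and 7360 by glmTreat.

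Some contigs set 1 hydroponic stage apart from both other groups. By definition the early sets include the 1369 contigs above that lay closer to the terrestrial level at the late stage. The late sets include the 243 that lay further from it, so these counts are not separate findings. Early roots were above both other groups in 1368 contigs (median 29.8 FPKM early, 16.18 late, 8.68 terrestrial) and below both in 1427 (3.73, 13.85 and 20.04 FPKM). Late hydroponic roots were above both in 827 contigs (median 3.11 FPKM early, 21.98 late, 3.42 terrestrial) and below both in 296 (18.92, 10.78 and 26.48 FPKM). With library totals alone the early sets held 851 and 2300 contigs and the late sets 962 and 193. Over all alternatives, early roots were above both in 318 to 2840 and below both in 485 to 2359 contigs, and late roots were above both in 422 to 1630 and below both in 45 to 768. The lowest counts came from glmTreat against 1.5-fold. The highest came from leaving out late hydroponic replicate 3 and terrestrial replicate 2 together (2840 and 768), an alternative added after the data were seen, from limma on log2(FPKM + 0.1) (2359) and from limma on log2(FPKM + 1) without a filter (1630). Contigs above both others in late roots numbered 535 with a minimum of 50 counts in 3 libraries and 529 with contigs under 500 bases left out, and DESeq2 gave 2345 contigs above both for early and 484 below both for late roots. Without early replicate 1, 2 and 3 in turn, early roots were above both in 543, 555 and 567 contigs and below both in 570, 767 and 605, and late roots were above both in 442, 515 and 479 and below both in 119, 107 and 148. Without late replicate 1, 2 and 3 in turn, the same sets held 637, 690 and 2446, then 779, 674 and 1562, then 514, 579 and 1107, and then 123, 159 and 555 contigs, and without terrestrial replicate 1 early roots were below both in 928.

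Contigs of the same assembly cluster moved in opposite directions less often than contigs with shuffled cluster numbers. Contigs of 1 cluster can be alleles or splice forms and can share reads, which ties their counts, and shuffling breaks that tie. A low count is therefore no sign of shared regulation. Of 2820 clusters with at least 2 tested contigs, 88 (3.1%) held both a higher and a lower contig in late hydroponic against terrestrial roots, where shuffled cluster numbers gave a mean of 402 (353 to 454). Early hydroponic against terrestrial roots gave 129 such clusters (4.6%), against a shuffled mean of 536.2 (483 to 590). Late against early hydroponic roots gave 10 (0.4%), against a shuffled mean of 39.1 (23 to 57). Each count lay below all 1000 shuffles, a one-sided permutation p of 0.001, the smallest that they can give. In 772 clusters for late hydroponic against terrestrial, 141 for late against early hydroponic and 921 for early hydroponic against terrestrial roots, all members called changed in 1 direction and more than 1 was called. Only clusters with at least 2 called contigs can hold both directions, and of the 860, 151 and 1050 such clusters, in the same order, 10.2, 6.6 and 12.3% held both. Shuffled cluster numbers gave mean shares of 53.3% (46.9 to 59.2), 50.8% (29.5 to 72.6) and 54.6% (49.5 to 59.7), each with a one-sided permutation p of 0.001. The late against early count was 3, 4 and 6 clusters without early replicate 1, 2 and 3, 29 without late replicate 3 and 17 without terrestrial replicate 2, and the late hydroponic against terrestrial count was 55 without terrestrial replicate 1.

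Late hydroponic libraries listed the most contigs, 35060 ± 223 (SD, n = 3), against 34181 ± 265 in early hydroponic and 33778 ± 262 in terrestrial libraries. Late hydroponic libraries exceeded terrestrial ones by 1283 and early ones by 879 contigs, each with an exact two-sided permutation p = 0.1, the smallest possible with 3 against 3. Early hydroponic libraries exceeded terrestrial ones by 403.7 contigs (exact two-sided permutation p = 0.2). At an FPKM of at least 1 there were 29881 ± 284 contigs in late hydroponic, 28369 ± 292 in early hydroponic and 28782 ± 592 in terrestrial libraries (SD, n = 3). The 100 contigs with the most counts were taken in each library. They held 17.1 ± 0.7% of counts in early hydroponic, 14.3 ± 1.4% in late hydroponic and 15.4 ± 1.4% in terrestrial libraries (SD, n = 3). The exact two-sided permutation p between groups lay between 0.1 and 0.5. The order of each kind of hydroponic library against terrestrial ones depended on the floor. Late minus terrestrial was -48 contigs with at least 5 counts (exact permutation p = 0.9) and -615 with an FPKM of at least 5 (exact permutation p = 0.2). Early minus terrestrial was -720.7 contigs with at least 5 counts and -2246 with an FPKM of at least 5, each with an exact two-sided permutation p = 0.1.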

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

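The counts of contigs that moved in opposite directions at the 2 hydroponic stages were drawn up after the comparisons were seen, and the ranges include 3 alternatives chosen after the data were seen. The contrast between the stages was fixed beforehand.

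Against terrestrial roots, 109 contigs were lower in early and higher in late hydroponic roots, which drew attention as a difference between the stages under 1 contrast. The late against early difference was called in every one of them by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Choosing contigs called in opposite directions in the same fit nearly fixes that outcome, so it is no separate support. Over the alternatives the count ran from 54 (glmTreat against 1.5-fold) to 160 (late hydroponic replicate 3 and terrestrial replicate 2 left out), and leaving out 1 library gave 73 to 149.

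The opposite pattern, higher in early and lower in late hydroponic roots than in soil, held in 24 contigs. The late against early difference was called in each, which the choice of contigs again nearly fixes. This count moved to 64 without late hydroponic replicate 3, to 15 without early hydroponic replicate 2 and to 11 without terrestrial replicate 1. Over the alternatives it ran from 3 (glmTreat against 1.5-fold) to 84 (late hydroponic replicate 3 and terrestrial replicate 2 left out). In the reported fit, each contig of either pattern also counts among those that set early roots apart and among those that set late roots apart. The cause of either pattern was not tested.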

How the results depend on the processing

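Leaving out late hydroponic replicate 3 with terrestrial replicate 2, leaving out contigs with under 3 counts throughout a group, and DESeq2 on the 26747 contigs were chosen after the data were seen. The named contigs kept their direction and their call in all 214 of their other alternatives and all 108 leave-one-out fits, with a highest adjusted p of 0.0358 (Unigene31091_mixA). The naming rule took the largest changes among called contigs whose groups did not overlap, which nearly fixes that outcome, so it is no separate support. The size of the change moved more: limma on log2(FPKM + 1) gave 6.68 for Unigene20764_mixA (11.10 in the reported fit), -6.41 for Unigene31091_mixA (-10.86), -6.40 for Unigene21847_mixA (-8.65) and 6.18 for CL1499.Contig1_mixA (8.06). Leaving out contigs with under 3 counts throughout a group removed Unigene31091_mixA and Unigene6328_mixA, which have no value there. No contig called both in the reported fits and in an alternative had the opposite sign. Stricter thresholds gave fewer calls by construction: a change of at least 1 on the log2 scale gave 2495 for late against early, 7831 at both stages, and 41, 4 and 69 clusters with opposite members in late against terrestrial, late against early and early against terrestrial roots. A test against 1.5-fold (glmTreat) gave 8892 for late against terrestrial, 1269 for late against early and 7360 at both stages. DESeq2 gave 29 such clusters for late against early, and the 2 libraries left out together gave 7145 contigs; the cause was not tested. Leaving out 1 library gave 12239 to 14027 contigs for late against terrestrial, 1598 to 5687 for late against early, 14617 to 17059 for early against terrestrial and 10145 to 11415 at both stages, and 55 to 82, 3 to 29 and 102 to 138 clusters in the first, second and last comparison. The late against early count of 3922 fell by over 1.5 times without any 1 early library or late replicate 1 or 2, each of which leaves fewer samples, and rose without late replicate 3. Detection differences changed sign with the floor: -48 (late minus terrestrial) and -720.7 (early minus terrestrial) with at least 5 counts, -615 (late minus terrestrial) with an FPKM of at least 5 and 470 (early minus terrestrial) with an FPKM of at least 0.1; the cause was not tested. Early minus terrestrial went from -412.7 with an FPKM of at least 1 to -2246 with at least 5. Thinning to 9499854 counts per library kept the signs. The gene lists were not run, since identifiers carry no names. At these depths and with 200 changed contigs, edgeR recovered 7.5 to 9% of simulated 2-fold changes, limma 3 to 9% and DESeq2 35.8 to 44.8%, the last with 55 to 67 false calls among 137 to 163. So few changed contigs make the adjusted cut-off stricter than in the data, so these shares do not carry over to the reported fits. How much of the low recovery is due to depth was not tested.

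Whether the replicate numbers pair the samples was not tested: deviations of same-numbered libraries correlated at -0.09 to 0.14, with 1 of 9 pairs over 0.1. Every early library correlated best with its own number among late libraries, and none did among terrestrial ones. Late replicates 2 and 3 correlated best with their own numbers among terrestrial libraries (0.06 and 0.14), and late replicate 1 did not (-0.09). With the number as a block the counts were 13572, 3093 and 15919 contigs for late against terrestrial, late against early and early against terrestrial roots and 11483 at both stages, with 73, 10 and 128 clusters, and no named contig lost its call, though the log2 change of Unigene6328_mixA moved from -12.67 to -14.64.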

Other observations

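The tests of the 3 patterns in single libraries were chosen after the patterns were seen, except the count of the same contig rule in the other hydroponic libraries, and so were the sets of contigs found in 1 group. The other splits of the libraries were planned.

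A few contigs were present in 1 kind of root and near absent from the others, with unlisted contigs taken as 0. With at least 10 counts in each library of a group and under 3 in every other library, 168 contigs were found in terrestrial roots alone, 121 in late hydroponic roots alone and 73 in early hydroponic roots alone. They held 0.08 to 0.22% of counts in terrestrial, 0.07 to 0.19% in late hydroponic and 0.03 to 0.05% in early hydroponic libraries. The reverse, at least 10 counts in each of 6 libraries and under 3 in each of the remaining 3, held for 167 contigs missing from terrestrial roots, 28 missing from early and 5 missing from late hydroponic roots. Unigene31091_mixA, with 1 count in each late hydroponic library and not listed in the early ones, was among the contigs of soil roots alone.

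The 100 contigs with the highest FPKM in each library were compared as well, a ranking other than the one by counts above. Pairs of early hydroponic libraries shared a mean of 87.7 of these, pairs of terrestrial libraries 81.7 and pairs of late hydroponic libraries 70.3 (67 to 73). Early and late hydroponic libraries shared 59.7 on average (47 to 72, which overlaps the late pairs), late hydroponic and terrestrial libraries 33.1 (28 to 38), and early hydroponic and terrestrial libraries 26.6 (22 to 31).

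In late hydroponic replicate 3, 43 contigs had at least 30 counts there and in each terrestrial library but under 3 in each other hydroponic library, Unigene6328_mixA among them. Counts near the thresholds were argued against, since the same rule gave at most 3 contigs with any other hydroponic library in place of late replicate 3. Carry-over of RNA from the 3 terrestrial samples of this series, alone or mixed, would bring their contigs at 1 share of the donor's level. As the only source of these contigs it was argued against, since each of 66 mixes of the soil libraries left contigs out of line. Between 11 and 31 contigs had under 3 counts where the median share of all contigs absent from the other hydroponic libraries gives 10 or more. At least 20 stood over 3 times their expected count. This test was rebuilt after its outcomes were seen, and among the shares tried the median was chosen to decide it. At the lowest share among the 43 contigs (2.4%), terrestrial replicate 2 alone left 2 contigs under 3 counts. Mixes with a weight of 0.8 or 0.9 for terrestrial replicate 2 left 3, each at its own lowest share. These are too few by the bound set to argue against carry-over. Terrestrial replicate 2 alone left 30 contigs over 3 times their expected count. No share from 1 to 100% left fewer than 21 contigs out of line in 1 way or the other for any mix. Contigs over their expected count could also have a source besides carry-over, so carry-over of part of these transcripts stayed open. Carry-over of RNA from another terrestrial sample stayed open, since soil libraries differed in such contigs and its profile is not known: set against the soil mean, levels ran from 4.2 to 97.5%, and 8 of 38 well-covered soil contigs had under 3 counts where the lowest share gives 10 or more. One further source of transcripts remained open too, as 42 of the contigs were higher in terrestrial replicate 3 than in 1. Their median log2 ratio of terrestrial replicate 3 to 1 was 1.31. In 10000 lists of like level, drawn from contigs found in every library, it was -0.13 to 0.18. The SD of the ratio was 0.43, against 0.32 in other contigs of like level, so they were no tighter. Plant contigs that vary together could also lie outside such lists, so the shift does not single out a further source. Such a source could be another organism or a plant genotype, which the contig identifiers cannot tell apart, and no biological explanation tied to the groups was tested.

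Terrestrial replicate 2 was low in contigs of soil roots alone: over 209 contigs with under 3 counts in each hydroponic library and at least 60 in the soil libraries together, the median log2 ratio to the mean of replicates 1 and 3 was -2.1, and 171 were lower, Unigene31091_mixA among them. Counting noise or a general shift of that library was argued against, since 10000 lists of like level gave medians of -0.27 to 0.06. A single other organism as the source of them all stayed open: the SD of the log2 ratio over 41 well-covered contigs was 1.47, against 0.36 from counting error, but the transcripts of 1 organism can also vary between samples. Several sources, or a plant response that varied among the soil samples, may also lie behind the pattern and were not tested.

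Late hydroponic replicate 3 lay nearer to the early libraries than late replicates 1 and 2 did, with a mean correlation of 0.908 with early libraries, against 0.871 and 0.884 for those replicates, and 0.927 with the other late ones. A label swap with an early library was argued against, since each early library correlated better with the other early libraries than with late ones, by at least 0.069. Early root RNA mixed into this sample could not be settled, because the test was changed after its outcomes were seen and its 3 forms gave different answers. The first found 4 of 78 late-stage contigs (5.1%) over 1.5 times both other late libraries, just past the 5% set as more than a mix would give. The same measure was 12.5% in late replicate 1 and 31% in late replicate 2, and the median log2 ratio to the other late libraries was -1.71 in replicate 3, against -0.25 and -0.03. Low levels of late-stage contigs could come from a mix or from a slower developing sample, so they decide nothing between these. The second, at 10-fold contrast, gave overlapping early shares of 33.1% (2.9 to 72.2, 6 early-stage contigs) and 69.5% (63.1 to 74.0, 78 late-stage contigs), as a mix would. The last, at 4-fold contrast, gave 27.6% (22 to 35.3, 92 contigs) and 63.8% (60.4 to 69.3, 284 contigs), which 1 mix would not, and a slower developing sample remains possible and untested.

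The 6 libraries of each comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05, and the real split alone, 1 of 10, gave as many calls as itself. The real split gave 14160 calls for late hydroponic against terrestrial roots and the highest other split 1. It gave 3922 for late against early hydroponic roots and the highest other split 0. It gave 16347 for early hydroponic against terrestrial roots and the highest other split 1. For contigs changed in the same direction at both stages, 1 of 60 splits of the 9 libraries drawn, the real one, gave as many as 11890. Splits that mix soil and hydroponic libraries within a group are nearly bound to give few calls, and not every split was drawn. The draw therefore cannot exclude that another grouping gives as many. The highest other split gave 10704, and it kept the 3 terrestrial libraries together while regrouping the hydroponic ones, so the count depended little on the division into stages in that split.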
